A study of Homo sapiens with 536 samples.

How the data were processed

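The series holds Affymetrix oligonucleotide arrays of the NCI-60 panel of established tumour cell lines after exposure to erlotinib. Per the labels' protocols, the drug was dissolved in DMSO, total RNA was isolated from the cultures, and biotin-labelled target was hybridised to the arrays. The 536 arrays cover 60 lines, 3 doses (0, 1000 and 10000 nM) and 3 times (2, 6 and 24 h), with 1 array per line, dose and time. Of the combinations of line, dose and time 4 were not analysed here, and the 9 groups held 59 or 60 arrays. The labels give the line, tissue, dose and time of each array and no batch or date.

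The deposited values are log2 signals, 1 per array and probe set, for 22277 probe sets. The method of background correction, summary and normalization that the authors used is not stated in the sources used here. Base 2 is taken from the range of the deposited values, 2.72 to 14.35. Array medians lay between 4.88 and 5.30 (SD 0.0742) and the quantiles of the arrays were close but not identical, so the values had been brought to a common scale between arrays. The values were used as deposited. No 2 arrays were identical, and no array was closest, over 5000 probe sets, to an array of another line, which checked the line labels. These correlations and the titles give the pairing by line.

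Of the probe sets, 19064 were annotated to 1 gene symbol, 1043 to several and 2164 to none, 62 controls included, and 19052 of the first had a gene identifier in the RefSeq annotation of GRCh38.p14, from which no symbol was changed. A gene was represented by the probe set, among those annotated to it alone, with the highest mean over all arrays. This gave 11963 genes, of which 4310 had more than 1 probe set. No filter on dim probe sets was used. AREG, ERRFI1, HMGCR, LDLR, CYP51A1, STAT1, HSPA1A, GBA1, BBC3, NOP56 and DHFR had no probe set of their own and were not analysed. No coordinates were used.

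Changes were computed within lines as the log2 signal of a treated array minus that of the 0 nM array of the same time. The doses were compared directly, the response to 10000 nM was compared between times as a difference of differences, and 0 nM arrays were compared between times. Each set of differences was fitted in limma 3.58.1 (R 4.3.3) with an intercept, moderated with a variance trend on the mean log2 expression of each gene, and tested on 2 sides with Benjamini-Hochberg adjustment over all genes. Genes with an adjusted p under 0.05 were called, and those with a mean change of at least 0.25 were counted apart. Tissue differences used the moderated F test over 9 tissues. The relation to baseline EGFR used a slope on the mean EGFR signal of the line's 0 nM arrays at the other 2 times, so that no array entered both sides. Choices made after first results had been seen were the variance trend, the division of lines by EGFR and the F test of the ATF4 score between tissues. The correlations of earlier scores with the G1/S score and the added checks named below were further such choices. On a matrix of differences, limma by default takes the mean change itself as the covariate of the variance trend, which gave a prior SD of up to 36.397 at 1000 nM and 24 h, against 0.312 with mean expression. Mean expression was therefore used, and the first version was kept as an alternative.

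Gene lists (24), the rule for named genes, the tests and most alternatives were fixed before the data were examined. The lists were ERK output, immediate early genes, ERBB receptors and ligands, G1/S and DNA replication, mitosis, p53 targets, cholesterol synthesis and uptake, fatty acid synthesis, aryl hydrocarbon receptor targets, FOXO targets and receptor feedback, ATF4 and unfolded protein response, heat shock, interferon response, NF-kB and inflammatory cytokines, BCL2 family, lysosome and autophagy, ribosome biogenesis, NRF2 targets, hypoxia and glycolysis, housekeeping, and melanocyte, blood cell, epithelial and mesenchymal markers. Lists could share genes, such as EGR1, IER3 and MYC in the ERK output and immediate early lists, so their scores are not independent. NQO1 is in the aryl hydrocarbon receptor and NRF2 lists. A list's score in a line was the mean change of its genes, tested over lines by 100000 random sign flips, with adjustment over lists and the 6 comparisons with 0 nM, and apart over lists and the other 8 comparisons. Members called in the gene-wise test are given over all genes and again adjusted over the list alone. Camera (limma) was run with a preset correlation between genes of 0.01 and with an estimated one. It asks whether a list changed more than the other genes, while the sign-flip test asks whether the list changed at all. The per-line score already keeps the correlation between genes. A call that ended with an estimated correlation in camera therefore does not mean that the list did not change. Genes named for a treatment are the 10 largest mean rises and falls among called genes that changed in that direction in at least 2 of every 3 lines. Other comparisons name the 5 largest each way, the tissue test its 10 smallest p, and each list up to 4 members with the largest change. EGFR, ERBB2, ERBB3, EREG, HBEGF, DUSP6, SPRY4, ETV5, EGR1, FOSL1, MYC and CCND1 could be named at any place.

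Correlations across lines (Pearson and Spearman) and between-tissue F statistics of scores used 100000 permutations (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9). Baseline EGFR was split at the widest gap (1.138) among the middle 80% of the ordered lines, since the widest gap over all lines (1.691) sets apart only 1 line. The use of clusters was fixed beforehand, but this rule for the division was chosen after the results were seen, so the values within and between clusters are post hoc. Correlations with baseline EGFR were taken over all lines and within the 2 clusters. After the results were seen, the tissue tests of the scores were repeated with each line left out in turn, adjusted over the 3 times, and each list score without the member that contributes most to it. Overlaps of calls are given beside the overlap of independent lists. For other splits of the samples, treated and untreated arrays were exchanged within random lines, or tissue or EGFR values were permuted over lines, with 100 splits each, the real one included.

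The alternatives were arrays minus their median, quantile normalisation, dim probe sets left out (above the array median in at least 10% of arrays, 8179 genes kept), the mean of a gene's probe sets, moderation without a variance trend, robust moderation, no pairing by line, 1 fit over all arrays with line and group as terms, 1 line of each related pair left out (NCI-ADR-RES, MDA-MB-435 and SNB-19), leukemia lines left out, the 3' over 5' signal of the GAPDH and ACTB controls as a covariate, and for EGFR its rank or tissue as a factor. List scores were also computed as medians and minus the all-gene median of the line. A further 2 alternatives were added after the data were seen, the variance trend on the mean change and the omission of 7 arrays with a GAPDH 3' minus 5' signal of at least 0.3.

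The fits were tested on simulated data built from the differences between 10000 nM and 0 nM at 24 h, with 200 changed genes in 5 runs. Of genes changed by 0.1, 0.25, 0.5 and 1 log2 unit, 34.0%, 93.6%, 100% and 100% were recovered. A run gave at most 29 false calls, which beside 200 changed genes is a larger share of the calls than 0.05. The 200 changed genes of 11963 were far fewer than the 4440 called in the real comparison, so recovery there may differ. The tissue test, with the renal lines shifted by 0.5 or 1, recovered 47.5% and 95.9%, with at most 19 false calls. EGFR slopes of 0.05, 0.1 and 0.2 were recovered in 56.0%, 96.1% and 99.9%, with at most 12. With no change, 6.5% of 480 sign-flip tests of lists gave an unadjusted p under 0.05. These data were themselves made by random sign flips of the centred scores, with the flips of a run shared by all 24 lists. A share near 0.05 therefore follows from the construction, and the test on real unchanged lists was not examined.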

Results

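Transcript levels were measured on 536 single-channel oligonucleotide arrays from 60 established human tumour cell lines of the NCI-60 panel. The cultures had been exposed to erlotinib, an inhibitor of the tyrosine kinase of the epidermal growth factor receptor (EGFR), at 0, 1000 or 10000 nM for 2, 6 or 24 h. The 0 nM cultures were the vehicle controls. The lines came from 9 tissues, with 9 lung, 9 melanoma, 8 renal, 7 colon, 7 ovarian, 6 breast, 6 central nervous system, 6 leukemia and 2 prostate lines. Every line contributed 1 array per dose and time, and 4 combinations of line, dose and time were not analysed here, so that each of the 9 groups held 59 or 60 arrays. The deposited values were log2 signals, and the array medians lay between 4.88 and 5.30. The purpose stated for the series was to compare transcriptional responses over time across the panel. Each change given here is the log2 signal of a treated array minus that of the 0 nM array of the same line and time, averaged over lines, with the SD over lines and the number of lines as n. A line had no second array at any dose and time, so p-values measure the spread between lines and the technical spread within a line is not known. The number of arrays limits the precision, and 11963 genes were tested in each comparison.

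The level of EGFR, the target of erlotinib, did not pass the test at any dose or time, with mean log2 changes from -0.002 ± 0.36 (1000 nM, 24 h, n = 59) to 0.047 ± 0.28 (10000 nM, 2 h, n = 58). At 1000 nM, a set of genes known to be transcribed in response to the kinase ERK was lower after 2 h. DUSP6, which encodes a phosphatase that inactivates ERK, had a mean log2 change of -0.35 ± 0.54 (SD, n = 59 lines) and was lower in 44 lines. SPRY4, a feedback inhibitor of receptor tyrosine kinase signalling, changed by -0.33 ± 0.50, and the ERK phosphatase DUSP5 by -0.26 ± 0.40. The immediate early genes EGR1 (-0.52 ± 0.99), JUNB (-0.22 ± 0.35), IER2 (-0.21 ± 0.36) and MAFF (-0.20 ± 0.38) fell as well, as did PHLDA1 (-0.22 ± 0.33), ZBED4 (-0.21 ± 0.25) and PTGER4, a prostaglandin receptor (-0.20 ± 0.31). HBEGF, a ligand of EGFR, changed by -0.18 ± 0.32 (adjusted p = 0.00485). Rises were small, led by CDKN2B, an inhibitor of cyclin-dependent kinases (0.13 ± 0.23), CFAP74 (0.11 ± 0.21), IFITM3 (0.09 ± 0.17), ABITRAM (0.08 ± 0.12) and IDH3B (0.07 ± 0.10). In all, 153 genes passed an adjusted p of 0.05, 16 higher and 137 lower, of which 0 and 4 changed by at least 0.25. With each array centred on its own median, 95 genes passed, 30 higher and 65 lower, and after quantile normalisation 121, 26 higher and 95 lower. A fit without the pairing by line called 0, and so did 1 fit over all arrays with line and group as terms. The calls of CFAP74 and IFITM3 ended when the variance trend ran on the mean change (adjusted p = 0.0604 and 0.0551).

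Of the 18 measured ERK output genes, 9 fell and 0 rose at 2 h (12 and 0 adjusted over the list alone). The per-line mean of this list was -0.16 ± 0.20 (n = 59) and lower in 45 lines (sign-flip permutation test, adjusted p = 3.89e-05, the smallest adjusted value these permutations gave). Immediate early genes changed by -0.15 ± 0.21, with 11 of 18 members lower and 1, KLF6, higher (15 and 1 adjusted over the list alone, adjusted p = 3.89e-05). The mitosis list changed by -0.043 ± 0.068, with 5 of 25 members lower, among them CCNB2 and KIF20A (13 adjusted over the list alone, adjusted p = 6.86e-05). The p53 target list changed by -0.050 ± 0.084, with 1 of 13 members lower, the death receptor gene TNFRSF10B (3 adjusted over the list alone, adjusted p = 6.86e-05). Further lists with a called score stayed under 0.05 in size, and each had at most 1 member called, HBEGF among ERBB receptors and ligands, MCL1 in the BCL2 family and VEGFA in the hypoxia list. Their calls ended in camera with an estimated correlation between genes, which sets a list against the other genes. The adjusted p of camera was 0.242 for ERBB receptors and ligands (-0.034), 0.315 for cholesterol synthesis (-0.023), and 0.392 for NF-kB and inflammatory cytokines (-0.045). It was 0.315 for the BCL2 family (-0.026), 0.132 for hypoxia and glycolysis (-0.028) and 0.052 for epithelial markers (0.028). Median-centring of the arrays also ended the calls of these lists except that of the epithelial markers.

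After 6 h at 1000 nM, the ERK output genes were lower on average, and genes of the ATF4 and FOXO lists were higher. DUSP5 changed by -0.51 ± 0.69, SPRY4 by -0.47 ± 0.74 and DUSP6 by -0.46 ± 0.93 (n = 59), and FOSL1, a component of the transcription factor AP-1, by -0.32 ± 0.54, lower in 52 lines. HBEGF (-0.32 ± 0.47), the cytokine gene LIF (-0.31 ± 0.48), the receptor kinase gene EPHA2 (-0.31 ± 0.47), the chemokine gene CXCL8 (-0.32 ± 0.55) and RGS2 (-0.24 ± 0.53) fell too. EGR1 changed by -0.63 ± 1.17 (adjusted p = 0.00169) and MYC by -0.20 ± 0.38 (adjusted p = 0.00286). CCNG2, an unconventional cyclin induced by FOXO factors, rose by 0.31 ± 0.54 in the mean, followed by the nuclear receptor NR1D2 (0.26 ± 0.40), and DDIT4, an inhibitor of mTORC1 signalling (0.26 ± 0.34). Smaller rises were those of PNRC1 (0.24 ± 0.35), the transcriptional repressor HBP1 (0.23 ± 0.29), CTH, an enzyme of cysteine synthesis (0.22 ± 0.31), CHAC1, an enzyme that degrades glutathione (0.22 ± 0.39), FZD2 (0.22 ± 0.39) and the lipid exporter ABCA1 (0.20 ± 0.40). The test called 402 genes, 143 higher and 259 lower, of which 3 and 12 changed by at least 0.25. Under median-centring the split was 105 higher and 317 lower, and without the pairing by line 0 genes were called. In 1 fit over all arrays, with line kept as a term, 10 genes were called, 0 higher and 10 lower.

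The ERK output list changed by -0.26 ± 0.44 at 6 h, with 12 of 18 members lower and 0 higher (16 and 0 adjusted over the list alone, adjusted p = 3.89e-05), and was lower in 44 of 59 lines. Immediate early genes changed by -0.14 ± 0.22, with 8 of 18 members lower (12 lower and 1 higher adjusted over the list alone, adjusted p = 3.89e-05). The ATF4 and unfolded protein response list rose by 0.096 ± 0.12, in 45 of 59 lines, with 7 of 17 members higher, among them HERPUD1 (0.16 ± 0.20) and DDIT3 (0.15 ± 0.27), and 12 adjusted over the list alone. FOXO targets and receptor feedback genes rose by 0.084 ± 0.14, with 4 of 17 members higher, CCNG2, the cyclin-dependent kinase inhibitor CDKN1B (0.17 ± 0.30), CITED2 and TXNIP (6 adjusted over the list alone). NF-kB and inflammatory cytokine genes changed by -0.10 ± 0.18, with CXCL8 and CXCL1 lower (5 adjusted over the list alone). These 5 calls held with an estimated correlation. Ribosome biogenesis genes changed by -0.049 ± 0.085, with 4 of 14 members lower, such as NOP16 and RRS1 (6 adjusted over the list alone, adjusted p = 0.0519 with an estimated correlation). Smaller scores whose calls ended with an estimated correlation were those of aryl hydrocarbon receptor targets (0.052, adjusted p = 0.0909), heat shock genes (-0.025, adjusted p = 0.154), ERBB receptors and ligands (-0.045, adjusted p = 0.315), the BCL2 family (-0.036, adjusted p = 0.198) and hypoxia and glycolysis genes (-0.023, adjusted p = 0.432).

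After 24 h at 1000 nM, the fall of ERK output genes was accompanied by lower levels of cell cycle genes and by higher levels of genes in the ATF4 and aryl hydrocarbon receptor lists. EGR1 changed by -0.87 ± 1.35 and DUSP6 by -0.61 ± 1.04 (n = 59), both lower in at least 43 lines. The call of EGR1 (adjusted p = 0.000553) ended with the first version of the test, in which the variance trend ran on the mean change (adjusted p = 0.797). ETV5, a transcription factor induced by ERK signalling, changed by -0.53 ± 1.00, SPRY4 by -0.43 ± 0.68, DUSP5 by -0.42 ± 0.78, FOSL1 by -0.42 ± 0.90 and CCND1, which encodes cyclin D1, by -0.33 ± 0.65. SLCO4A1 (-0.34 ± 0.69), PHLDA2 (-0.33 ± 0.62) and the replication factors MCM10 (-0.31 ± 0.53) and CDT1 (-0.30 ± 0.41) fell as well. CYP1A1, a cytochrome P450 induced through the aryl hydrocarbon receptor, rose by 0.52 ± 1.08 (adjusted p = 0.316 with the first version of the test), the stress protein gene NUPR1 by 0.38 ± 0.65, PCK2, a mitochondrial enzyme of gluconeogenesis, by 0.35 ± 0.46, and the histone gene H2AC6 by 0.34 ± 0.60. TSC22D3, a glucocorticoid-induced gene, rose by 0.32 ± 0.41, higher in 52 lines. ASNS, which makes asparagine, rose by 0.31 ± 0.42, and CHAC1, DDIT4, PBXIP1 and TNNC1 by 0.29 to 0.32. The receptor gene ERBB3 rose by 0.14 ± 0.41 (adjusted p = 0.0456) and the ligand gene EREG fell by 0.21 in the mean (SD 0.62, adjusted p = 0.0486), calls that both ended when the probe sets of a gene were averaged. The test called 1654 genes, 593 higher and 1061 lower, of which 27 and 26 changed by at least 0.25. A fit without the pairing by line called 0, and 1 fit over all arrays with line and group as terms called 810.

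Of the 18 ERK output genes, 16 fell at 24 h and 0 rose (17 and 0 adjusted over the list alone), with a list score of -0.33 ± 0.52, lower in 43 of 59 lines (adjusted p = 3.89e-05, and adjusted p = 0.0697 with an estimated correlation). Genes of G1/S and DNA replication changed by -0.17 ± 0.31, with 20 of 22 members lower (22 adjusted over the list alone, adjusted p = 3.89e-05, and adjusted p = 0.104 with an estimated correlation). Mitosis genes changed by -0.15 ± 0.30, with 22 of 25 members lower, among them MKI67 (-0.23 ± 0.40) and AURKB (-0.21 ± 0.38) (24 adjusted over the list alone, adjusted p = 0.161 with an estimated correlation). The lists that rose with calls that held under an estimated correlation were the ATF4 list (0.15 ± 0.19, 11 of 17 members higher and 1, the chaperone cofactor gene SDF2L1, lower) and 2 more. These were the aryl hydrocarbon receptor targets (0.19 ± 0.32, 4 of 7 members higher, with CYP1B1 at 0.35 ± 0.65) and the NRF2 targets (0.098 ± 0.15, 6 of 10 members higher, with HMOX1 at 0.20 ± 0.36). Adjusted over the list alone, 12, 5 and 7 of their members were higher, and SDF2L1 was lower. Interferon response genes rose by 0.11 ± 0.19, with 8 of 17 members higher, such as IRF9 (0.22 ± 0.43) (9 adjusted over the list alone, adjusted p = 0.0509 with an estimated correlation). Further called scores were those of ribosome biogenesis (-0.11), heat shock (-0.067), immediate early (-0.065, or -0.017 without EGR1) and housekeeping genes (-0.027), and of FOXO targets (0.098), epithelial markers (0.080) and lysosome and autophagy genes (0.068). Each of these calls ended with an estimated correlation, at adjusted p = 0.105, 0.11, 0.623, 0.198, 0.166, 0.0898 and 0.132 in that order.

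**Figure D1:**
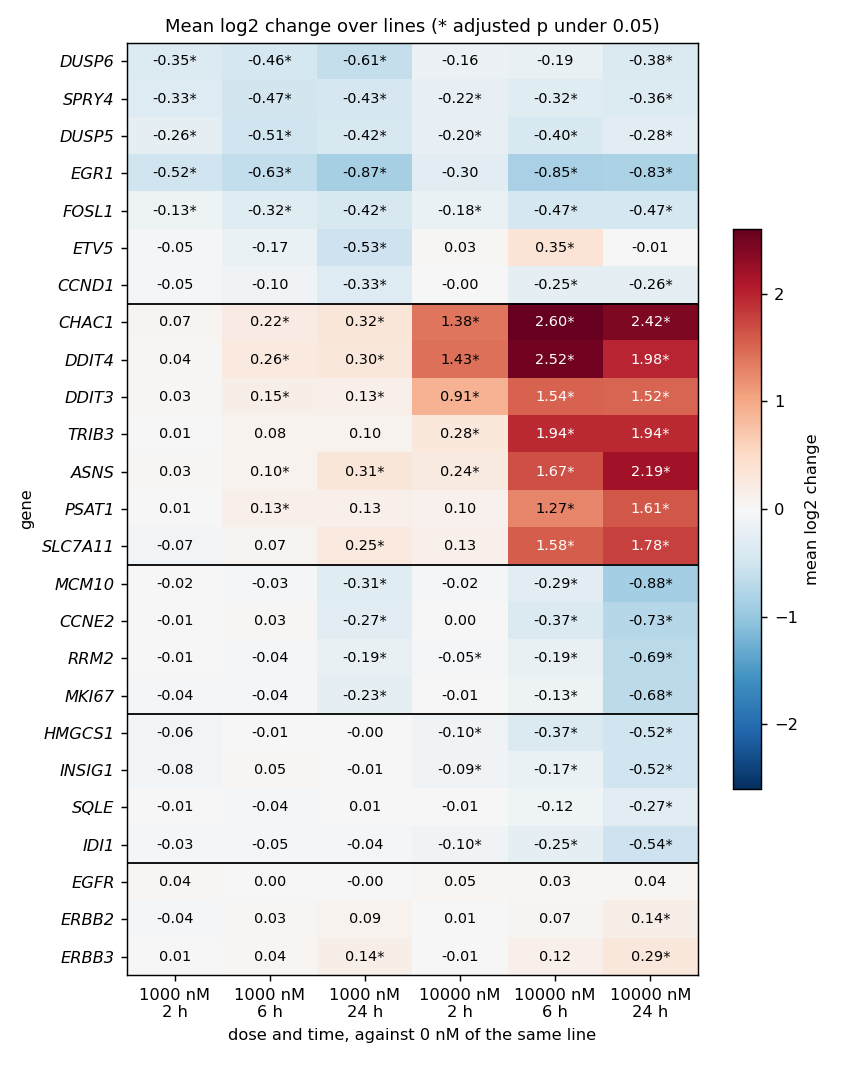
Heat map of the mean log2 change over cell lines for 25 genes (vertical axis) at each dose and time against 0 nM (horizontal axis), with the value in every cell and an asterisk where the adjusted p was under 0.05. The stress genes CHAC1 and DDIT4 reached 2.60 and 2.52 at 10000 nM and 6 h, against 0.22 and 0.26 at 1000 nM.

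At 10000 nM, the leading change after 2 h was a rise of stress-response genes. DDIT4 rose by 1.43 ± 1.19 (n = 58) and CHAC1 by 1.38 ± 1.15, higher in 51 and 55 lines. DDIT3, which encodes the transcription factor CHOP, rose by 0.91 ± 0.54, TSC22D3 by 0.52 ± 0.48, and the secreted glycoprotein gene STC2 by 0.39 ± 0.50. Genes of transcription factors rose as well, ATF3 by 0.39 ± 0.52, CEBPB by 0.34 ± 0.33, KLF6 by 0.32 ± 0.30 and ATF4 by 0.32 ± 0.21, the last in 57 lines. CCNG2 rose by 0.33 ± 0.48. CCN2 (-0.34 ± 0.47) and CCN1 (-0.25 ± 0.43), which encode matricellular proteins, led the falls, followed by ZNF264 (-0.24 ± 0.37), HIC2 (-0.22 ± 0.27), HSPA2 (-0.22 ± 0.32) and ZNF107 (-0.21 ± 0.32). Of the ERK output genes, DUSP5 (-0.20 ± 0.44) and FOSL1 (-0.18 ± 0.34) fell. DUSP6 (-0.16 ± 0.63, adjusted p = 0.297) and EGR1 (-0.30 ± 1.22, adjusted p = 0.307) did not pass the test, and MYC rose by 0.15 ± 0.28 (adjusted p = 0.00158). The test called 378 genes, 139 higher and 239 lower, of which 15 and 1 changed by at least 0.25. A fit without the pairing by line called 3 genes, and 1 fit over all arrays called 34.

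The ATF4 list rose by 0.35 ± 0.27 at 2 h and in 54 of 58 lines, with 9 of 17 members higher and SDF2L1 lower (14 and 1 adjusted over the list alone, adjusted p = 3.89e-05). FOXO targets rose by 0.070 ± 0.11, with 4 of 17 members higher, led by CCNG2 and CDKN1B (0.30 ± 0.32), and 6 higher and 1 lower adjusted over the list alone (adjusted p = 0.000131). Mitosis genes changed by -0.040 ± 0.069, with 7 of 25 members lower (14 adjusted over the list alone, adjusted p = 0.000131). The ERK output list changed by -0.079 ± 0.24, with 4 of 18 members lower and MYC higher (6 and 1 adjusted over the list alone, adjusted p = 0.0282, and adjusted p = 0.291 with an estimated correlation). Cholesterol synthesis genes changed by -0.036 ± 0.081, with 5 of 17 members lower, such as MSMO1 (-0.12 ± 0.17) and HMGCS1, the enzyme that makes HMG-CoA (-0.099 ± 0.21) (5 adjusted over the list alone, adjusted p = 0.00172, and adjusted p = 0.117 with an estimated correlation). The score of the immediate early genes was not called (-0.079 ± 0.27, adjusted p = 0.057), with ATF3, MYC and KLF6 higher and 5 members lower.

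After 6 h at 10000 nM, CHAC1 was higher in 60 of 60 lines, by 2.60 ± 1.08, and DDIT4 in 60 of 60, by 2.52 ± 1.36. TRIB3, a pseudokinase induced by amino acid and endoplasmic reticulum stress, rose by 1.94 ± 0.85, PCK2 by 1.72 ± 0.84, and ASNS by 1.67 ± 0.76. SLC7A11, the cystine transporter, rose by 1.58 ± 0.89, DDIT3 by 1.54 ± 0.76, CTH by 1.53 ± 1.02, TSC22D3 by 1.32 ± 0.90 and the serine synthesis enzyme PSAT1 by 1.27 ± 0.60. The falls were smaller and led by JMJD6 (-0.51 ± 0.34), FOSL1 (-0.47 ± 0.74), and DUSP7, an ERK phosphatase (-0.45 ± 0.41). They included RBM12 (-0.44 ± 0.23, lower in 59 of 60 lines), ZNF143 (-0.42 ± 0.25), RGS2 (-0.42 ± 0.56), FASTKD5 (-0.41 ± 0.24), and CDC25A, a phosphatase that promotes entry into S phase (-0.41 ± 0.29). EGR1 changed by -0.85 ± 1.36 and CCND1 by -0.25 ± 0.40, while ETV5 rose by 0.35 ± 0.55 in the mean and in 46 lines. VEGFA, the angiogenic growth factor gene, rose by 0.99 ± 0.62. The test called 2704 genes, 977 higher and 1727 lower, of which 161 and 121 changed by at least 0.25, and a fit without the pairing by line called 57.

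Of the 17 measured ATF4 and unfolded protein response genes, 16 rose and SDF2L1 fell at 6 h (16 and 1 adjusted over the list alone), and the list score was 1.17 ± 0.46 and above 0 in 60 of 60 lines (adjusted p = 3.89e-05). Among its members, HSPA5, the main chaperone of the endoplasmic reticulum, was among the smallest rises, at 0.13. NRF2 targets rose by 0.23 ± 0.16, with 7 of 10 members higher (8 adjusted over the list alone). SLC7A11 belongs to both lists and makes up most of this score, which was 0.085 ± 0.13 without it, above 0 in 45 of 60 lines (adjusted p = 3.89e-05). The next of these members were HMOX1 (0.30 ± 0.57) and the thioredoxin reductase gene TXNRD1 (0.13 ± 0.19). FOXO targets rose by 0.19 ± 0.18, with 8 of 17 members higher, among them CCNG2 (0.87 ± 0.61) and KLF9 (0.57 ± 0.57) (9 adjusted over the list alone). Heat shock genes fell by 0.19 in the mean (SD 0.12), in 58 of 60 lines, with 7 of 9 members lower, such as DNAJA1 (-0.37 ± 0.24) and BAG3 (-0.31 ± 0.26) (8 adjusted over the list alone). These 4 calls, each at adjusted p = 3.89e-05, held with an estimated correlation. Other called lists did not hold with it. They were G1/S and DNA replication (-0.084, 10 of 22 lower and 1 higher, adjusted p = 0.104), cholesterol synthesis (-0.10, 8 of 17 lower, adjusted p = 0.212) and ribosome biogenesis (-0.10, 9 of 14 lower, adjusted p = 0.0852), and, with rises, lysosome and autophagy genes (0.070, 7 of 16 higher and 1 lower, adjusted p = 0.13) and aryl hydrocarbon receptor targets (0.056, 2 of 7 higher, adjusted p = 0.205). Adjusted over each list alone, 11, 10 and 10 members of the first 3 were lower, and 9 and 2 of the others were higher.

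The ERK output list changed by -0.17 ± 0.46 at 6 h, with 8 of 18 members lower and ETV5 higher (8 and 1 adjusted over the list alone, adjusted p = 0.00606, and adjusted p = 0.667 with an estimated correlation). The remaining scores were small. Immediate early genes changed by -0.080, or -0.034 without EGR1 (10 of 18 members lower and 2 higher, adjusted p = 0.594 with an estimated correlation), fatty acid synthesis genes by -0.040 (adjusted p = 0.692 with it) and housekeeping genes by -0.024 (adjusted p = 0.56 with it). The hypoxia list had a mean of 0.046 ± 0.11 (-0.033 without VEGFA) with VEGFA and NDRG1 higher and ADM, PFKFB3 and HK2 lower, a score taken as the median over members was -0.003, and its adjusted p was 0.913 with an estimated correlation. Scores of the immediate early, fatty acid synthesis and housekeeping lists were not called after median-centring.

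After 24 h at 10000 nM, genes of the ATF4 list were high and those of the cell cycle lists low. CHAC1 rose by 2.42 ± 1.00 (n = 59), PCK2 by 2.19 ± 0.93, ASNS by 2.19 ± 0.82, and DDIT4 by 1.98 ± 1.26. TRIB3 rose by 1.94 ± 0.85, SLC7A11 by 1.78 ± 0.99, NUPR1 by 1.77 ± 1.47, the serine synthesis genes PHGDH by 1.69 ± 0.87 and PSAT1 by 1.61 ± 0.68, and DDIT3 by 1.52 ± 0.74. MCM10 fell by 0.88 in the mean (SD 0.97), the kinetochore gene SPC25 by 0.75 (SD 0.83), the transcription factor gene E2F8 by 0.74 (SD 0.69), and CCNE2, which encodes cyclin E2, by 0.73 (SD 0.87). The noncoding gene DLEU2 fell by 0.73 (SD 0.56) and SDF2L1 by 0.70 (SD 0.50). RRM2, a subunit of ribonucleotide reductase (-0.69 ± 0.89), ERCC6L (-0.69 ± 0.69), the proliferation marker gene MKI67 (-0.68 ± 0.65) and the replication factor GINS2 (-0.65 ± 0.82) followed. ERBB3 rose by 0.29 ± 0.51 and ERBB2 by 0.14 ± 0.35. The test called 4440 genes, 2154 higher and 2286 lower, of which 554 and 450 changed by at least 0.25. Under median-centring the split was 1714 higher and 3134 lower, and a fit without the pairing by line called 273 genes.

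Of 22 G1/S and DNA replication genes, 22 fell at 24 h (22 adjusted over the list alone), with a list score of -0.49 ± 0.60, lower in 55 of 59 lines (adjusted p = 3.89e-05, and adjusted p = 0.183 with an estimated correlation). All 25 mitosis genes fell (25 adjusted over the list alone), with a score of -0.44 ± 0.53, lower in 51 of 59 lines (adjusted p = 3.89e-05, and adjusted p = 0.177 with an estimated correlation). PLK1 (-0.60 ± 0.64), KIF11 (-0.57 ± 0.66) and CDC6 (-0.62 ± 0.93) were among the larger falls. The ATF4 list rose by 1.18 ± 0.41 in 59 of 59 lines, with 15 of 17 members higher and SDF2L1 lower (15 and 1 adjusted over the list alone). NRF2 targets rose by 0.55 ± 0.30 in 58 of 59 lines, with 10 of 10 members higher, such as HMOX1 (0.75 ± 0.85), AKR1C1 (0.68 ± 0.85) and NQO1 (0.52 ± 0.42). Heat shock genes changed by -0.26 ± 0.18, with 9 of 9 lower. Adjusted over the list alone, 10 of the NRF2 targets were higher and 9 of the heat shock genes lower. The calls of these 3 lists, each at adjusted p = 3.89e-05, held with an estimated correlation.

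Lipid synthesis genes were lower at 24 h. Of 17 cholesterol synthesis genes 16 fell (16 adjusted over the list alone), among them ACAT2 (-0.55 ± 0.54), IDI1 (-0.54 ± 0.46), HMGCS1 (-0.52 ± 0.59) and INSIG1 (-0.52 ± 0.66). The score was -0.31 ± 0.30 and lower in 50 of 59 lines (adjusted p = 3.89e-05, and adjusted p = 0.104 with an estimated correlation). Fatty acid synthesis genes changed by -0.17 ± 0.23, with 6 of 8 lower, led by FASN, the fatty acid synthase (-0.57 ± 0.47). ME1, which makes NADPH, was higher at 0.37 ± 0.45. Of this list 7 were lower and 1 higher adjusted over the list alone, and its score had adjusted p = 3.89e-05, and adjusted p = 0.212 with an estimated correlation. Lysosome and autophagy genes rose by 0.22 ± 0.20, with 11 of 16 higher and 2 lower (11 and 2 adjusted over the list alone), such as the autophagy receptor SQSTM1 (0.57 ± 0.45) and MAP1LC3B (0.52 ± 0.38) (adjusted p = 3.89e-05, and adjusted p = 0.104 with an estimated correlation). FOXO targets rose by 0.21 ± 0.27, with 13 of 17 higher, such as TXNIP (0.50 ± 0.80) and KLF9 (0.48 ± 0.52) (13 adjusted over the list alone, adjusted p = 0.183 with an estimated correlation). Aryl hydrocarbon receptor targets rose by 0.37 ± 0.41, with 6 of 7 higher, CYP1A1 at 0.69 ± 1.37 and CYP1B1 at 0.52 ± 0.86 (7 adjusted over the list alone, adjusted p = 0.0519 with an estimated correlation). NQO1 belongs to this list and to the NRF2 targets, so these scores are not independent. Ribosome biogenesis genes changed by -0.16 ± 0.24, with 11 of 14 lower (11 adjusted over the list alone, adjusted p = 0.257 with an estimated correlation).

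The ERK output list changed by -0.23 ± 0.59 at 24 h, with 10 of 18 members lower (11 adjusted over the list alone, adjusted p = 0.00672, and adjusted p = 0.641 with an estimated correlation), and was lower in 34 of 59 lines. EGR1 (-0.83 ± 1.49) and FOSL1 (-0.47 ± 1.09) changed most, and ETV5 had a mean of -0.015 ± 1.16 (adjusted p = 0.948). Of the p53 targets, GADD45A (0.56 ± 0.58), TNFRSF10B (0.29 ± 0.35), TP53I3, CDKN1A and XPC rose and BAX, FAS and AEN fell, at a score of 0.057 (adjusted p = 0.651 with an estimated correlation). In the BCL2 family, whose score of 0.030 was not called (adjusted p = 0.117), the proapoptotic genes PMAIP1 (0.62 ± 0.64) and HRK (0.29 ± 0.53) rose and BID, BAX and BAK1 fell. The interferon list was not called (0.062 ± 0.23, adjusted p = 0.0756), and the hypoxia list was not either (-0.002 ± 0.19, adjusted p = 0.96), with VEGFA at 1.06 ± 0.72. NF-kB and cytokine genes (0.097, adjusted p = 0.594 with an estimated correlation), ERBB receptors and ligands (0.063, adjusted p = 0.449 with it) and epithelial markers (0.084, adjusted p = 0.561 with it) rose slightly. Housekeeping genes changed by -0.089 ± 0.082, with 8 of 11 lower and B2M and GUSB higher (adjusted p = 0.124 with an estimated correlation), HPRT1 at -0.28 ± 0.30. Among lineage markers, the blood cell list changed by -0.033 with CORO1A alone called (adjusted p = 0.736 with an estimated correlation), and the melanocyte (-0.038 ± 0.16, adjusted p = 0.136) and mesenchymal (0.003 ± 0.11, adjusted p = 0.91) lists were not called. The calls of the p53, ERBB and NF-kB lists ended under median-centring.

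**Figure D2:**
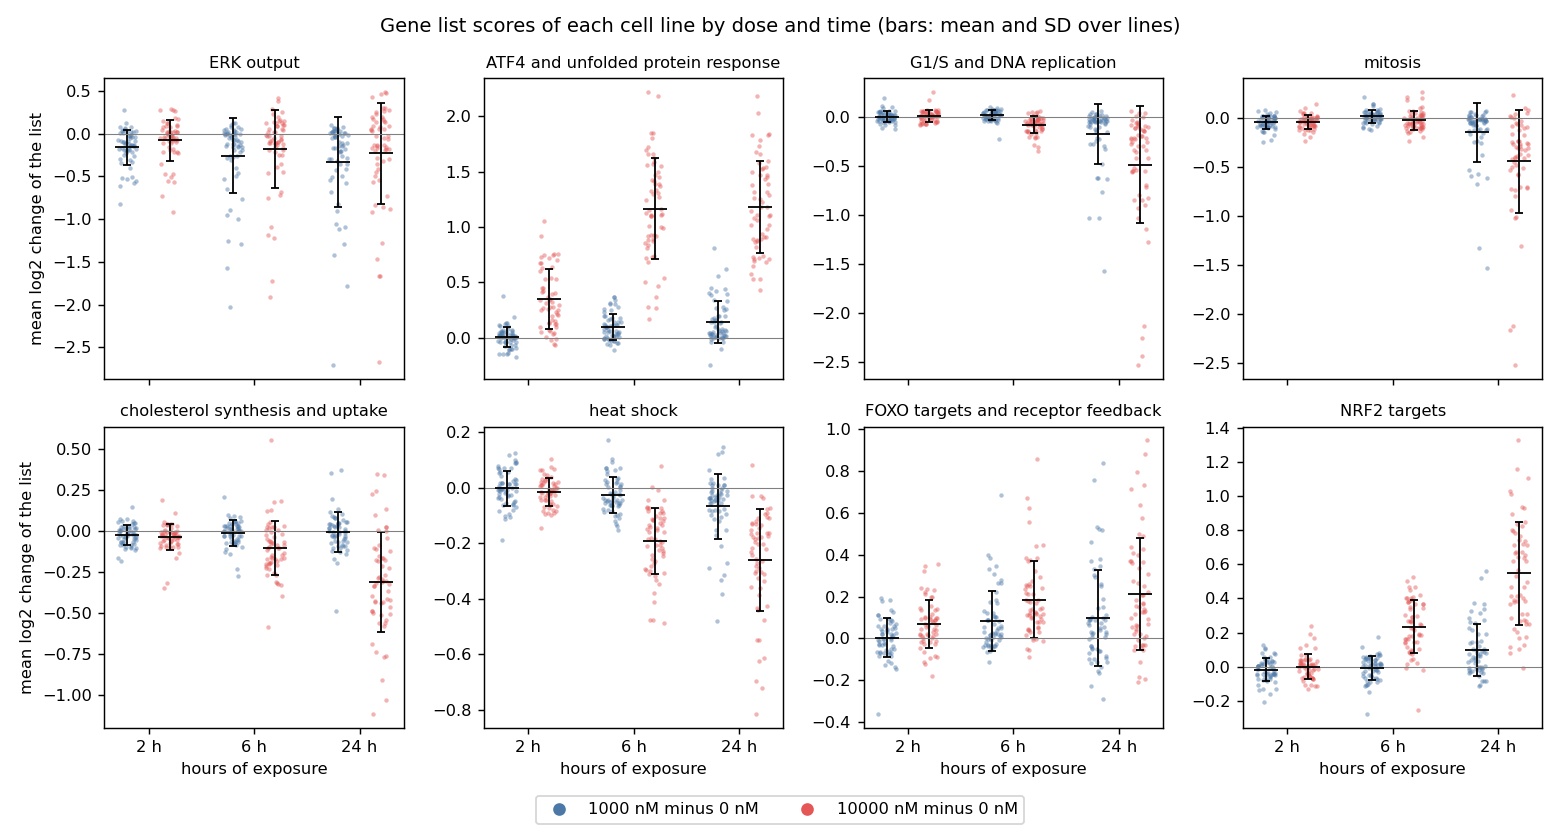
Per-line scores (mean log2 change of a list's genes against 0 nM, vertical axes) for 8 gene lists by hours of exposure (horizontal axes), with 1 point per cell line, blue for 1000 nM and red for 10000 nM, and bars for the mean and SD over lines. The ATF4 scores at 10000 nM and 6 h lay above 0 in 60 of 60 lines, with a mean of 1.17.

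The direct comparison of the doses asked which genes responded differently to 10000 nM than to 1000 nM. It does not use the 0 nM arrays. Higher at 10000 nM were DDIT4 (1.38 ± 1.04), CHAC1 (1.29 ± 1.08) and DDIT3 (0.88 ± 0.51) at 2 h (n = 59), and CHAC1 (2.38 ± 0.95), DDIT4 (2.23 ± 1.27) and TRIB3 (1.86 ± 0.76) at 6 h (n = 59). At 24 h they were CHAC1 (2.11 ± 0.90), ASNS (1.89 ± 0.82), TRIB3 (1.85 ± 0.76) and PCK2 (1.85 ± 0.83, n = 60). Lower at 10000 nM were SKP2 (-0.13 ± 0.18) and CDC25A (-0.12 ± 0.20) at 2 h, RBM12 (-0.45 ± 0.23), ZNF107 (-0.45 ± 0.40), CCNE2 (-0.41 ± 0.30) and HMGCS1 (-0.38 ± 0.33) at 6 h. At 24 h they were MCM10 (-0.57 ± 0.64), SPC25 (-0.55 ± 0.56), ACAT2 (-0.53 ± 0.46) and SDF2L1 (-0.53 ± 0.38). The number of genes called was 156 at 2 h (131 higher and 25 lower), 2539 at 6 h (879 and 1660) and 3694 at 24 h (1864 and 1830). Median-centring gave 97 higher and 40 lower at 2 h, 1084 and 1300 at 6 h, and 1549 and 2407 at 24 h, and quantile normalisation gave 108 and 47 at 2 h and 1094 and 1353 at 6 h. Without the pairing by line the counts were 2, 46 and 71. With line kept as a term in 1 fit over all arrays they were 20 at 2 h and 1568 at 6 h.

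Several ERK output genes were less lowered, or higher, at the larger dose. DUSP6 was higher at 10000 nM than at 1000 nM by 0.19 ± 0.30, 0.27 ± 0.54 and 0.24 ± 0.62 at 2, 6 and 24 h, and MYC by 0.22 ± 0.23, 0.25 ± 0.32 and 0.15 ± 0.30. ETV5 was higher by 0.51 ± 0.45 at 6 h and 0.52 ± 0.68 at 24 h. In contrast, FOSL1 (-0.15 ± 0.37) and CCND1 (-0.16 ± 0.28) were lower at 10000 nM at 6 h. The ERK output list score was higher at 10000 nM by 0.079 ± 0.12 at 2 h (adjusted p = 3.31e-05). It was higher by 0.084 ± 0.22 at 6 h (adjusted p = 0.00745, adjusted p = 0.328 with an estimated correlation, and 0.059 without ETV5 at adjusted p = 0.0618) and by 0.099 ± 0.26 at 24 h (adjusted p = 0.00873, and adjusted p = 0.525 with an estimated correlation). It was higher in 46 of 59, 38 of 59 and 42 of 60 lines. At 2 h 3 of the 18 members were higher and 0 lower, at 6 h 8 and 3, and at 24 h 7 and 1, or 6 and 0, 9 and 4, and 8 and 1 adjusted over the list alone.

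Responses to 10000 nM were also compared between times within lines, each time with its own 0 nM array. Between 2 and 6 h the response of PCK2 rose by 1.65 ± 0.82 (n = 58), of TRIB3 by 1.63 ± 0.80, of SLC7A11 by 1.46 ± 0.89, of ASNS by 1.45 ± 0.64 and of CTH by 1.44 ± 0.95. The response of EGR1 (-0.54 ± 1.00), ZNF143 (-0.41 ± 0.29) and JMJD6 (-0.39 ± 0.37) became more negative. Between 6 and 24 h the response of ASS1, an enzyme of arginine synthesis, rose by 0.94 ± 0.93 (n = 59), of the protease inhibitor gene CSTA by 0.91 ± 1.13, of PHGDH by 0.87 ± 0.65, of NIBAN1 by 0.79 ± 0.80 and of CBS by 0.73 ± 0.77. That of SPC25 (-0.66 ± 0.85), DLEU2 (-0.65 ± 0.56), MCM10 (-0.60 ± 0.95) and the DNA repair gene RAD54L (-0.57 ± 0.55) became more negative. The test called 1325 genes between 2 and 6 h (570 higher and 755 lower), 2377 between 6 and 24 h (1375 and 1002) and 3318 between 2 and 24 h (1652 and 1666). Median-centring gave 932 higher and 1593 lower between 6 and 24 h and 1269 and 2309 between 2 and 24 h, and the counts without the pairing by line were 10, 0 and 27. The fit over all arrays called 553 between 2 and 6 h. The 6 and 24 h calls at 10000 nM shared 729 genes that were higher at both times and 1065 that were lower at both, where independent lists of these sizes would share 175.9 and 330.0. At 1000 nM the corresponding numbers were 45 and 115, against 7.1 and 23.

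In vehicle alone, expression also changed with time in culture. Between 2 and 6 h at 0 nM the transcription factor genes KLF11 (-1.12 ± 0.56), ATF3 (-1.03 ± 0.76) and MNT (-0.83 ± 0.42) fell. ZNF322 (0.81 ± 0.49), the ubiquitin ligase gene RNF111 (0.74 ± 0.31) and DDIT4 (0.66 ± 0.68) rose (n = 59). Between 2 and 24 h ATF3 (-1.43 ± 0.91), CCN2 (-1.34 ± 0.93), MAFF (-1.27 ± 1.08), KLF11 (-1.19 ± 0.55) and SMAD7 (-1.18 ± 1.04) fell. DDIT4 (1.57 ± 0.99), ZNF322 (0.97 ± 0.53), WDR5B (0.85 ± 0.44) and RSBN1 (0.76 ± 0.46) rose (n = 58). Heat shock genes were lower at 6 h than at 2 h (-0.24 ± 0.11, 9 of 9 members, adjusted p = 3.31e-05). Immediate early genes were lower at 24 h (-0.54 ± 0.46, 14 of 18 members lower and 1 higher, adjusted p = 3.31e-05), and both calls held with an estimated correlation. Adjusted over the list alone, 9 heat shock genes were lower, and 15 immediate early genes were lower and 1 higher. The test called 3029 genes between 2 and 6 h (1556 higher and 1473 lower) and 3758 between 2 and 24 h (2243 and 1515), against 48 and 85 without the pairing by line. After median-centring of the arrays 1863 were higher and 1216 lower between 2 and 6 h, and 2006 and 1685 between 2 and 24 h, so the share of rises depends on the normalization. These changes do not enter the treated-minus-vehicle values, which are taken within a time.

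The tissue comparison asked whether the response to 10000 nM differed with the origin of a line. HBEGF at 6 h had the smallest adjusted p of that time (F = 13.32, adjusted p = 3.56e-07, limma moderated F test over 9 tissues), with mean changes of 0.83 in colon lines and -1.0 in renal lines. The collagen receptor gene DDR2 had means of 0.97 in melanoma and 0.84 in central nervous system lines at 6 h against -0.29 in leukemia lines, and CLIC4 of 1.14 in colon lines against 0.16 in breast lines. EGR1 changed by -2.58 in ovarian and -1.75 in renal lines and by 0.12 in melanoma lines at 6 h (adjusted p = 0.00253). At 24 h CDH19 (0.96), SCRG1 (1.47) and NNMT (1.69) were higher in melanoma lines, TM6SF1 (1.99) and ATF5 (1.82) in leukemia lines, ALOX5AP in renal (1.39) and leukemia lines (0.89), and ASNS ranged from 1.36 in breast to 3.08 in melanoma lines. The F test called 2 genes at 2 h (DKK1 and AMOTL2), 17 at 6 h and 53 at 24 h, and at an unadjusted p under 0.05 it gave 532, 989 and 1520. About 598 are expected at that threshold by chance, so the 532 at 2 h are no excess. The 2 h count was 0 under 5 alternatives and 1 without the leukemia lines, the 6 h count was 8 with probe sets averaged, and the 24 h count was 27 without 1 line of each related pair.

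The ERK output score at 10000 nM differed between tissues at 2 h (F = 3.52, permutation test, adjusted p = 0.013), 6 h (F = 2.20, adjusted p = 0.0488) and 24 h (F = 2.15, adjusted p = 0.0488). The calls at 6 and 24 h are fragile. Left out 1 at a time, after the results were seen, 40 of 60 lines ended the call at 6 h (adjusted p up to 0.109, without SK-OV-3) and 41 that at 24 h (up to 0.115, without IGR-OV1), while that at 2 h was kept without any of them. At 24 h the score was -0.81 ± 0.53 in ovarian lines, lower in 7 of 7. It was -0.53 ± 0.90 in lung lines, lower in 7 of 9, and -0.26 ± 0.43 without NCI-H322M, lower in 6 of 8. It was 0.10 ± 0.11 in colon lines, higher in 5 of 6, and 0.072 ± 0.14 in melanoma lines, higher in 6 of 9. Without the leukemia lines the differences at 6 and 24 h were not called (both adjusted p = 0.0622). The tissue difference of the ATF4 score, a test added after the results were seen, was not called at 2 h (F = 0.73, adjusted p = 0.662) and was called at 6 h (F = 2.48, adjusted p = 0.0344) and 24 h (F = 3.75, adjusted p = 0.00504). The call at 6 h ended without any 1 of DU-145, IGR-OV1, MCF7, NCI-H226, OVCAR-3, SK-OV-3 and T-47D (adjusted p up to 0.0733), and that at 24 h was kept without any line. At 24 h it was highest in ovarian (1.58 ± 0.32), colon (1.44 ± 0.47) and melanoma lines (1.39 ± 0.25) and lowest in breast lines (0.75 ± 0.18).

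**Figure D3:**
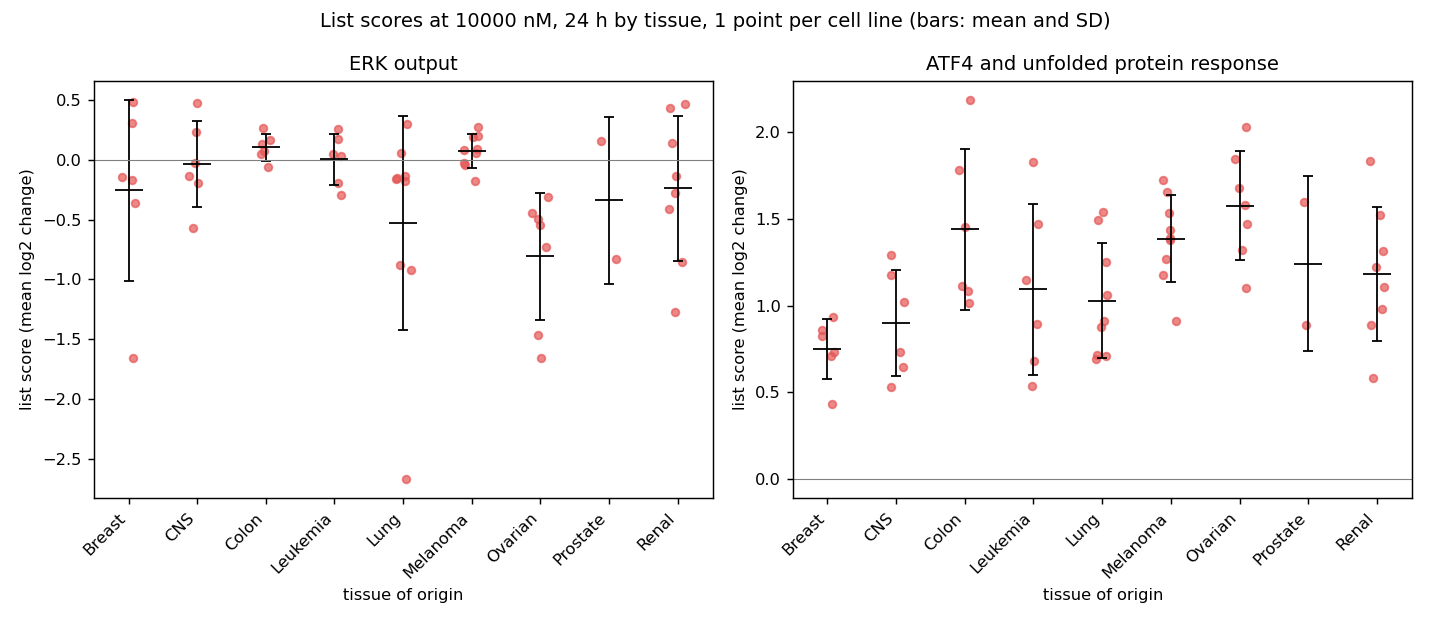
Scores of the ERK output list (left) and of the ATF4 and unfolded protein response list (right) at 10000 nM and 24 h (vertical axes, mean log2 change) by tissue of origin (horizontal axes), with 1 point per cell line and bars for the mean and SD. The 7 ovarian lines lay below 0 for ERK output, and every line lay above 0 for the ATF4 list.

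Because EGFR is the target of erlotinib, responses were set against the EGFR signal of each line at 0 nM, which ranged from 3.93 to 13.25 on the log2 scale. No gene's response to 1000 nM followed baseline EGFR after adjustment at 2, 6 or 24 h (limma, 0 genes at each time), with 673, 770 and 1759 genes at an unadjusted p under 0.05 where 598 were expected by chance. Among the genes that could be named at any place, EGR1 came closest at 24 h, with a slope of -0.26 per log2 unit of EGFR (SE 0.055, adjusted p = 0.0671). DUSP6 (-0.17, SE 0.044, adjusted p = 0.0755), ETV5 (-0.18, SE 0.042, adjusted p = 0.0689) and SPRY4 (-0.12, SE 0.029, adjusted p = 0.069) also had negative slopes that did not pass. With the rank of EGFR in place of its signal, 199 genes passed at 24 h, and with probe sets averaged 148. At 10000 nM 0 genes passed at 2 h and at 6 h (635 and 1186 unadjusted). At 24 h 3 did (1256 unadjusted), SLC17A5, a lysosomal sialic acid transporter (slope 0.089), CPB2 (0.042) and ATF5 (-0.16), each at adjusted p = 0.0423. With tissue as a factor 55 genes passed at 2 h and 0 at 24 h, and without 1 line of each related pair 0 passed at 24 h.

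Split at the widest gap among the middle 80% of its ordered values, baseline EGFR lay between 3.93 and 5.04 in 15 lines and between 6.18 and 13.25 in 45 lines, and the relation to the ERK output score was taken within each cluster. This division was chosen after the results were seen, so values that use the clusters are post hoc. Over all lines, without the division, r was -0.36, -0.41 and -0.46 at 1000 nM and 2, 6 and 24 h (adjusted p = 0.0105, 0.00327 and 0.0012, n = 59) and rho -0.43, -0.55 and -0.49 (adjusted p = 0.0018, 6e-05 and 0.00048). At 10000 nM r was -0.18, -0.20 and -0.31 (adjusted p = 0.177, 0.14 and 0.0236, n = 58, 60 and 59) and rho -0.13, -0.29 and -0.28 (adjusted p = 0.314, 0.036 and 0.036). These values mix differences between the clusters with those within them. Within the 45 lines with more EGFR signal, the score at 1000 nM was lower where EGFR was higher at 2 h (Pearson r = -0.45, permutation p = 0.00253, adjusted p = 0.00759, Spearman rho = -0.47, permutation p = 0.00136, adjusted p = 0.00681, n = 44). It was also lower at 24 h (r = -0.47, p = 0.00181, adjusted p = 0.00759, rho = -0.45, p = 0.00227, adjusted p = 0.00681, n = 44). At 6 h r was -0.28 (p = 0.0648, adjusted p = 0.0928) and rho -0.34 (p = 0.023, adjusted p = 0.0345). At 10000 nM r in these lines was -0.26, -0.26 and -0.35 at 2, 6 and 24 h, with adjusted p = 0.0928, 0.0928 and 0.0408, and rho was -0.26, -0.37 and -0.32, with adjusted p = 0.0874, 0.0283 and 0.0442. Without the 2 lines farthest from the median EGFR, r was -0.37, -0.19 and -0.39 at 1000 nM and -0.24, -0.16 and -0.29 at 10000 nM. Each dose and time counts as 1 relation in a family of 6. Across the 44 lines of both clusters from tissues other than leukemia and melanoma, r at 1000 nM was -0.28, -0.24 and -0.38 at 2, 6 and 24 h and did not pass (adjusted p = 0.19, 0.225 and 0.0757). Spearman rho there was -0.41, -0.27 and -0.38 (adjusted p = 0.0316, 0.116 and 0.0357). At 10000 nM r there was -0.090, -0.088 and -0.22 (adjusted p = 0.57, 0.57 and 0.236, n = 43, 45 and 44) and rho -0.15, -0.28 and -0.20 (adjusted p = 0.346, 0.116 and 0.228). In the 15 lines with little EGFR signal no relation passed (lowest adjusted p = 0.357 for r and 0.682 for rho). Their EGFR signals, 3.93 to 5.04, lay below or within the range of the array medians (4.88 to 5.30). With so few lines and so narrow a range, this test could hardly find a relation and decides nothing. Averaging the probe sets of each gene ended the called values of r at 1000 nM and 2 h (-0.28, adjusted p = 0.161), 1000 nM and 24 h (-0.43, adjusted p = 0.0952) and 10000 nM and 24 h (-0.31, adjusted p = 0.161). Median-centring ended the last of these (-0.33, adjusted p = 0.0573).

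**Figure D4:**
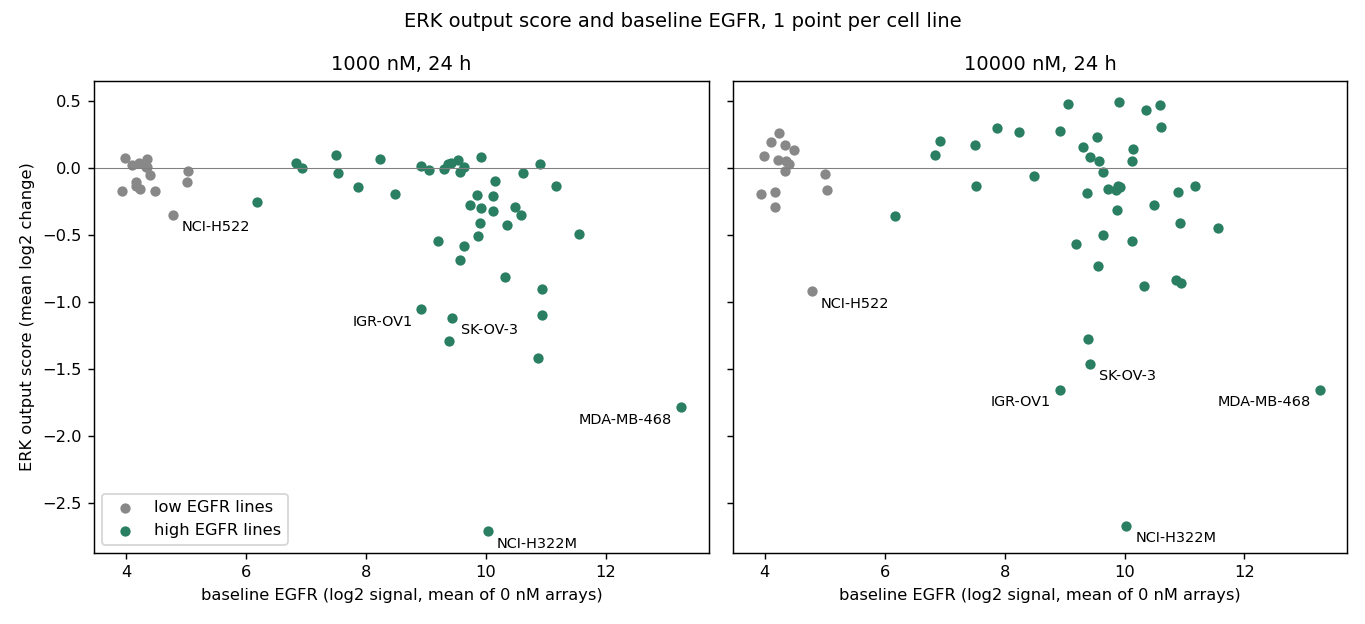
ERK output score (vertical axis, mean log2 change against 0 nM) against baseline EGFR (horizontal axis, log2 signal averaged over 0 nM arrays) for each cell line at 24 h, at 1000 nM (left) and 10000 nM (right), with the lines of low EGFR signal in grey. Within the green points r was -0.47 at 1000 nM, and the lung line NCI-H322M had the lowest score at both doses (-2.71 and -2.67).

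Between the clusters, divided post hoc, the mean ERK output score at 1000 nM and 24 h was -0.072 ± 0.12 in 15 lines with little EGFR signal and -0.42 ± 0.58 in 44 lines with more. This difference did not pass a permutation test after adjustment over 6 comparisons (adjusted p = 0.0696). Nor did that at 6 h (-0.016 ± 0.14 against -0.34 ± 0.48, adjusted p = 0.064). The other comparisons in this permutation test lay farther from the threshold. Their adjusted p was 0.297 at 1000 nM and 2 h, and 0.581, 0.534 and 0.297 at 10000 nM and 2, 6 and 24 h. The ATF4 score at 10000 nM and 24 h was 1.21 ± 0.44 in the 15 lines and 1.17 ± 0.41 in 44 lines (adjusted p = 0.837). The ERK output scores of the lines at 10000 nM were correlated between times, although each time had its own 0 nM array. The correlation r was 0.77 between 2 and 6 h (rho = 0.75, n = 58), 0.89 between 6 and 24 h (rho = 0.79, n = 59) and 0.74 between 2 and 24 h (rho = 0.73, n = 57), each with permutation p = 1e-05, the smallest these permutations can give, and adjusted p = 1e-05 over 3 relations. For the ATF4 list the values were 0.60 (rho = 0.67), 0.81 (rho = 0.80) and 0.48 (rho = 0.53), with permutation p of at most 0.00023 and adjusted p of at most 0.00023. Without the 2 lines farthest from the median, r was 0.84, 0.83 and 0.74 for ERK output and 0.59, 0.77 and 0.54 for the ATF4 list.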

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

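In this part, the tests of normalization for the ATF4 list and of an array from another line for NCI-H522, the choice of the EGFR probe set that separates the clusters, the division of the lines at the widest gap among the middle 80% of the ordered EGFR values, the F test of the ATF4 score between tissues and the omission of each line from the tissue tests and of 1 member from each list were chosen after the result was seen.

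The rise of the ATF4 and unfolded protein response list at 10000 nM, seen in all 59 lines at 24 h, was weighed first. If inhibition of EGFR were its cause, lines with little EGFR signal should rise by less than 0.2, but the 15 lines of the low cluster had a mean score of 1.21 (SD 0.44, 95% interval from 0.967 to 1.454), which argues against it. Loss of RNA integrity, as measured by the 3' over 5' control signal, is excluded as the whole cause, since the mean was 1.172 (SE 0.054) at equal signal. A shift common to all genes is not the whole cause either, with 1.188 (lower 95% limit 1.081) after each line's all-gene median change was subtracted. Those median changes lay between -0.135 and 0.077, so the subtraction could hardly lower the mean. It does not test other effects of normalization. A candidate explanation is an effect of the larger dose on a target other than EGFR that activates ATF4, and no test here names that target. Differences in this score between tissues stay open as well.

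NCI-H522, a lung line with a baseline EGFR signal of 4.78 in the low cluster, lowered its ERK output score at 10000 nM by 0.563, 1.226 and 0.922 at 2, 6 and 24 h, and by 0.549, 0.398 and 0.354 at 1000 nM. An array from another line is excluded, as 9 of 9 arrays were closest to another array of the line, but an exchange of doses within the line was not tested. A probe set that misses the EGFR transcript cannot be told apart from a low level, because on the 1 of 5 other EGFR probe sets that separates the clusters the line lay at 4.872, between the highest other low line (4.754) and the lowest high line (5.137). Before that restriction the prediction was met by 1 probe set, on which the clusters overlap. Signal from another ERBB receptor may explain the response, since baseline ERBB4 was 10.48, above 100% of the other lines (median of the lines 3.83), and ERBB2 was 8.63, above 96.6% (median 6.67), while ERBB3 was 3.85, above 35.6%.

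The ERK output score was less lowered at 10000 nM than at 1000 nM, by 0.088 over the 3 times (95% interval from 0.046 to 0.131, higher in 43 of 60 lines). With an estimated correlation between genes its call ended at 6 h (adjusted p = 0.328) and 24 h (adjusted p = 0.525) and held at 2 h (adjusted p = 0.00466), and without ETV5 the per-line call ended at 6 h (adjusted p = 0.0618). Without EGR1, IER3, PHLDA1, LIF and MYC the difference was 0.07638 (0.033 to 0.120, 41 lines), so these stress-responsive members are not the whole cause. A shift common to all genes is not the whole cause either, with 0.09141 (0.049 to 0.133, 44 lines) after subtraction of each line's all-gene median. The median over genes of the mean dose difference was only 0.0033, -0.0070 and -0.0069 at 2, 6 and 24 h. The subtraction could therefore remove little, and it does not test other effects of normalization. No biological explanation was tested.

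Within the lung lines, NCI-H322M stood far from the others in ERK output score at 10000 nM and 24 h, at -2.670 against -0.922 to 0.296 in the other 8, a gap of 0.589 of the range. It was the only flag in 48 groups of lines of a tissue examined in this way. Chance gives about 1 in 20, so 1 flag is no more than chance would give. The line's score at 1000 nM and 24 h was -2.711, taken from the same 0 nM array as that at 10000 nM. At 6 h, with a separate 0 nM array, the score was -2.024 at 1000 nM and -1.906 at 10000 nM.

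The response to 10000 nM differed between times within lines in 1325 genes for 6 h against 2 h, 2377 for 24 h against 6 h and 3318 for 24 h against 2 h. When treated and untreated arrays were exchanged within random lines, only the real split of 100 gave as many genes in each of the 3. The highest other counts were 1, 6 and 3, which argues against chance, at shares that were not adjusted over the 3 comparisons.

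Differences between tissues were called for 2, 17 and 53 genes at 2, 6 and 24 h. At 2 h 7 of 100 permutations of tissue over lines, the real one included, gave at least 2 genes (highest other 7), so chance is not excluded. At 6 h 4 of 100 gave as many (highest other 31) and at 24 h 2 of 100 did (highest other 453), shares that were not adjusted over the 3 times. The 453 genes of 1 permutation, several times the real 53, may reflect a structure of the lines that the tissue labels do not describe or correlation between genes, which was not tested. The ERK output score differed between tissues with F = 3.52, 2.20 and 2.15 at 2, 6 and 24 h, and the ATF4 score with F = 2.48 at 6 h and 3.75 at 24 h (permutation tests in the report). The ERK output calls at 6 and 24 h ended without any 1 of 40 and 41 of 60 lines, and the ATF4 call at 6 h without any 1 of 7, while the calls at 2 h for ERK output and at 24 h for ATF4 were kept.

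Outside the gene-wise comparisons, 140 of 3151 probe sets with several or no gene symbol were called at 10000 nM and 24 h with a change of at least 0.25 (780 called at any size, largest change 0.971), against 0 of 45 bacterial and phage control probe sets (1 called at any size).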

How the results depend on the processing

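All alternatives were chosen beforehand except the omission of arrays with high GAPDH 3' over 5' signal, the variance trend on the mean change, the omission of each line from the tissue tests and the omission from each list of the member that contributes most, which were chosen after the results were seen. For each changed result below the cause was not tested, unless stated. Over 23 counts of genes, the alternatives chosen beforehand left 188 values within 1.5 times and moved 50, and the added ones left 43 and moved 3. Of the values of 354 named genes, those chosen beforehand kept 3560 on their side of the threshold and in direction, brought 27 past it and took 305 below it (the added ones 688, 3 and 17). Of those 305, 185 came from the fit without pairing. Of 336 list scores, 2689 values stayed, 52 passed, 278 no longer passed and 5 reversed, and without the member that contributes most 286 stayed, 41 no longer passed and 9 reversed. Of 24 relations across lines 112 stayed, 2 passed and 6 no longer passed (99, 0 and 81 of the 180 added). Robust moderation, run for the 14 paired counts and not for those of tissue or EGFR, moved none of them. Signal over background could not be measured, since no detection calls were used, and dim genes are limited by it.

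Without the replicate block, that is without the pairing by line, counts fell because differences between lines enter the spread. They were 0, 0 and 0 at 1000 nM (2, 6 and 24 h), 3, 57 and 273 at 10000 nM and 2, 46 and 71 for the dose difference. They were 10 (6 against 2 h), 0 (24 against 6 h) and 27 (24 against 2 h) for the response over time, and 48 and 85 in vehicle. With all arrays in 1 fit the counts were 0, 10 and 810 at 1000 nM, and 34 at 10000 nM and 2 h. They were 20 and 1568 for the dose difference at 2 and 6 h, and 553 for the response at 6 against 2 h. With median-centred arrays 95 genes were called at 1000 nM and 2 h.

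Tissue counts at 2 h were 0 with the mean of a gene's probe sets, without a variance trend, with related lines left out, with high GAPDH arrays left out and with the variance trend on the mean change, and 1 with leukemia lines left out. They were 8 at 6 h with the mean of probe sets and 27 at 24 h with related lines left out. For baseline EGFR at 1000 nM, the mean of probe sets gave 1, 10 and 148 genes at 2, 6 and 24 h and the rank of EGFR 5 at 6 h and 199 at 24 h. At 24 h there were also 1 with median-centred arrays, 36 with dim probe sets left out, 3 with related lines left out, 21 with the 3' over 5' covariate and 103 with high GAPDH arrays left out. At 10000 nM the counts at 2 h were 1 with leukemia lines left out and 55 with tissue as a factor, and at 6 h 1 each with the mean of probe sets, related lines left out and leukemia lines left out. At 24 h they were 11 with median-centred arrays, 5 with quantile normalisation, 12 with dim probe sets left out, and 10 with the mean of probe sets. They were 6 without a variance trend, 0 with related lines left out, 7 with leukemia lines left out and 0 with tissue as a factor.

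Camera with an estimated correlation gave adjusted p = 0.0697 for the ERK output list at 1000 nM and 24 h and 0.291, 0.667 and 0.641 at 10000 nM and 2, 6 and 24 h. With the median over the list's genes, the hypoxia score reversed to -0.003 at 10000 nM and 6 h (adjusted p = 0.886), -0.056 for the dose difference at 24 h (adjusted p = 0.0169) and -0.001 for 6 against 2 h (adjusted p = 0.958). The BCL2 family score reversed to -0.018 and -0.007 for the dose difference at 6 and 24 h (adjusted p = 0.209 and 0.616). Members of these lists moved both ways, and the omission of 1 member reversed these scores as well. Without the member that contributes most, the hypoxia score reversed without VEGFA. It was -0.033 at 10000 nM and 6 h (adjusted p = 0.0259), -0.013 and -0.069 for the dose difference at 6 and 24 h (adjusted p = 0.321 and 0.00217), and -0.007 and -0.066 for 6 and 24 h against 2 h (adjusted p = 0.747 and 0.0238). The BCL2 family score without PMAIP1 was -0.029 and -0.019 for the dose difference at 6 and 24 h (adjusted p = 0.0642 and 0.183). In vehicle, 24 h against 2 h, the ERBB score was 0.020 without HBEGF (adjusted p = 0.326) and the ATF4 score -0.021 without DDIT4 (adjusted p = 0.46). Correlations of ERK output with EGFR in the high cluster were -0.334 with median-centred arrays (10000 nM, 24 h, adjusted p = 0.0573) and -0.326 with quantile normalisation (10000 nM, 2 h, adjusted p = 0.0498). With the mean of probe sets they were -0.278 (1000 nM, 2 h, adjusted p = 0.161), -0.430 (1000 nM, 24 h, adjusted p = 0.0952) and -0.314 (10000 nM, 24 h, adjusted p = 0.161). Outside leukemia and melanoma that mean gave -0.431 (1000 nM, 24 h, adjusted p = 0.0304). With leukemia lines left out, F for ERK output by tissue was 2.153 at 6 h and 2.091 at 24 h (both adjusted p = 0.0622). With each of the 60 lines left out in turn, F lay between 1.877 and 2.673 at 6 h and between 1.703 and 2.639 at 24 h. The call ended without any 1 of 40 lines at 6 h (adjusted p up to 0.109) and 41 at 24 h (up to 0.115), because both lay close to the threshold, and it was kept throughout at 2 h (2.824 to 4.325).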

Other observations

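The list comparisons in this part were planned, except that of a list without 1 member, chosen after the results were seen. The rules for the G1/S correlations and for the splits were written before those tests were run. The G1/S rule was set for a fall already seen. The lists give further values for the comparison of the doses, for the time course and for vehicle alone, each by the sign-flip permutation test over lines. At 10000 nM the ATF4 list was higher than at 1000 nM by 0.344 ± 0.255 at 2 h (in 56 of 59 lines), 1.066 ± 0.413 at 6 h (59 of 59) and 1.041 ± 0.382 at 24 h (60 of 60). NRF2 targets were higher by 0.238 ± 0.132 at 6 h and 0.445 ± 0.274 at 24 h, in 59 of 59 and 58 of 60 lines. SLC7A11, also in the ATF4 list, carried most of the 6 h value, and without it the scores were 0.101 ± 0.118 and 0.325 ± 0.278. Heat shock genes were lower by 0.169 and 0.198 in the mean, each in 58 lines. G1/S genes were lower by 0.098 in the mean at 6 h already, in 55 of 59 lines and with 14 of 22 members called. Each of these values had adjusted p = 3.31e-05, the smallest adjusted value these permutations gave. Those of the whole lists held with an estimated correlation, which was not run without SLC7A11. At 24 h, mitosis (-0.298 ± 0.327), G1/S (-0.314 ± 0.370) and cholesterol synthesis genes (-0.301 ± 0.294) were lower at the larger dose, and aryl hydrocarbon receptor targets (0.173 ± 0.193) and lysosome and autophagy genes (0.149 ± 0.133) higher. These calls ended with an estimated correlation (adjusted p = 0.0887, 0.114, 0.0582, 0.0582 and 0.055).

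Over time at 10000 nM, the response of the ATF4 list rose by 0.814 ± 0.371 between 2 and 6 h, in 58 of 58 lines, and its further change to 24 h was not called (0.02, adjusted p = 0.662). Between 6 and 24 h the responses of NRF2 targets (0.316 ± 0.270) and of aryl hydrocarbon receptor targets (0.314 ± 0.341) rose, each in 52 of 59 lines, and that of cholesterol synthesis genes fell by 0.205 in the mean (SD 0.256), lower in 47 of 59. These calls held with an estimated correlation (adjusted p = 0.00241, 0.0102 and 0.0292). In vehicle alone, 24 h against 2 h, NF-kB and cytokine genes changed by -0.394 ± 0.475 and ribosome biogenesis genes by -0.156 ± 0.170. Fatty acid (0.238 ± 0.232) and cholesterol synthesis genes (0.229 ± 0.246) rose. None of these 4 held with an estimated correlation (adjusted p = 0.0887, 0.0621, 0.0645 and 0.121).

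Differences between lines in the fall of G1/S genes at 24 h may follow the earlier fall of ERK output. Across lines, the ERK output score at 6 h and the G1/S score at 24 h, which share no array and no gene, correlated with Spearman rho = 0.6482 at 1000 nM (n = 58, Pearson r = 0.806, and r = 0.781 without the 2 lines farthest from the median). At 10000 nM rho was 0.5412 (n = 59, r = 0.8289, and 0.717 without 2 lines), and adjusted permutation p was at most 4.5e-05 at both doses. The prediction of a correlation above 0.3 was met at both doses, and a line's general sensitivity to the drug would give the same relation. The order of the doses went the other way in the lines with more EGFR signal, divided post hoc. Their ERK output score at 6 h was -0.34 at 1000 nM and -0.20 at 10000 nM. Their G1/S score at 24 h was -0.22 and -0.57. In the 15 lines with little EGFR signal these scores were -0.094 and -0.26 at 10000 nM, G1/S lower in 13. This argues against the earlier fall of ERK output as the whole cause of the fall at 10000 nM. An earlier rise of the ATF4 list at 10000 nM gave rho = -0.2317 (permutation p = 0.0763, n = 59). Pearson r was -0.308 (permutation test, adjusted p = 0.0178), and -0.220 without the 2 lines farthest from the median. The prediction of a negative rho of more than 0.3 in size with permutation p under 0.05 was not met. By the rule set before this test was run, an earlier ATF4 rise as the explanation is not supported, and a weaker relation is not excluded.

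Chance was examined for the other counts of genes with 100 splits each, the real one included. For the 6 comparisons with 0 nM, the 3 dose differences and the 2 vehicle comparisons, only 1 split, the real one, gave as many genes. This argues against chance, at shares that were not adjusted over these comparisons. The exchange of arrays does not test differences in handling between the groups compared. The highest other counts were 1, 1 and 1 at 1000 nM (real 153, 402 and 1654), and 1, 1 and 3 at 10000 nM (real 378, 2704 and 4440). They were 2, 7 and 1 for the dose difference (real 156, 2539 and 3694). They were 2 and 36 in vehicle (real 3029 and 3758). For baseline EGFR the count of splits decides nothing where the real count is 0, at 1000 nM (highest other 1 at each time) and at 10000 nM and 2 and 6 h (highest other 1 and 3), since all 100 splits reach 0. The 3 genes at 10000 nM and 24 h were reached in 2 of 100, a share under 0.05 without adjustment for the 6 EGFR comparisons. The 3 calls fell to 0 with related lines left out and to 0 with tissue as a factor. A permutation that called 176 may reflect a structure of the lines other than EGFR or correlation between genes, which was not tested.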
